A study of Menidia beryllina with 23 samples.

How the data were processed

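RNA from whole inland silversides (Menidia beryllina, a small fish that lives in both fresh and salt water) was measured on 23 single-colour Agilent arrays of a custom design. Per the labels' protocols, the fish were exposed for 14 d to nominal bifenthrin concentrations of 0.5, 5 or 50 ng/L or to the methanol solvent alone. Whole fish were homogenized, RNA was extracted with RNeasy Plus Mini Kits, and 200 ng of total RNA per sample was amplified and labelled with Cy3 by the Low Input Quick Amp kit in reactions run at the same time. Groups and replicate codes were taken from the sample titles and treatment labels. There were 7 control arrays, 4 at 0.5 ng/L, 5 at 5 ng/L and 7 at 50 ng/L. Sex, body size and tank are not given in the labels, and nothing says that the fish of a group came from separate tanks, so p-values measure the spread between these samples.

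Per the file headers, spot intensities were extracted with Agilent Feature Extraction 11.5.1.1 under the protocol GE1_1105_Oct12. The deposited intensity used here was the processed signal, which is background-corrected by that software. The authors' deposited value table, on a log2 scale, held 9058 probes, 21% of the 43179 probes that are not array controls. Its scale and centring are not given in the sources used here and were worked out from the values. Each of its columns correlated with the quantile-normalized log2 processed signal of the same array, centred on the median of each probe over the 23 arrays, at r of at least 0.998. Each probe's median in that table was 0. The rule by which the authors chose those probes stays unknown.

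The main values were log2 processed signals minus the 75th percentile of each array, so a level of 0 is the 75th percentile of that array's probes. Each array held 44596 spots, of which 1417 were control spots and were left out. Values with an outlier flag (182 in all) were left out of the main fit, and 17 saturated values were kept. Flagged values were left out only after a first fit that kept them had been seen, with 71 probes past the threshold in the trend and 0 at 50 ng/L, against 6 and 1 with them left out. A probe was tested when it was well above background on at least 4 arrays, which left 37244 probes and excluded 5935. Of the tested probes, 27690 were well above background on all 23 arrays. The 75th percentile of the processed signal was 100.1 ± 14.4 (SD, n = 7) in the controls, 84.1 ± 21.1 (n = 4) at 0.5 ng/L, 85.9 ± 10.1 (n = 5) at 5 ng/L and 84.6 ± 14.2 (n = 7) at 50 ng/L. Between 32008 and 36401 probes per array were well above background, and Spearman correlations between arrays ranged from 0.872 to 0.972. No arrays held identical values. The number of arrays limits the precision.

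Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 23 arrays, with Benjamini-Hochberg adjustment over the probes tested and a threshold of adjusted p of 0.05. The comparisons were each concentration against control, each pair of concentrations, the F test of the 4 groups, and a trend over the concentration rank (control 0, then 1, 2 and 3). Fold changes of the concentrations were correlated across probes, beside 100 simulations of unchanged groups against the same number of controls and beside all 70 ordered divisions of the controls into parts of 3 and 4. Where a probe was not well above background on any array of the dimmer group, its fold is a bound. The bound sets the brighter group's mean against a floor averaged over the dimmer group's arrays. On each array that floor is the higher of the probe's own level and the lowest level among probes well above background. Probes above that lowest level can also fail to be well above background, so the bound is not a strict limit.

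The files pair no probe with a gene name, and no probe annotation was used here. The gene lists planned for fish tissues and hormone responses, the test of those lists and the planned use of an oocyte list as a covariate could therefore not be run. By the rule set before the data were examined, probes without a gene name are named by their identifier, up to 2 per direction and comparison, by smallest p.

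The 23 arrays lay on 6 slides, which were the same sets of arrays as 6 scan runs in the file headers, over 3 scan days. Each slide held more than 1 group, but slides 4 and 6 held no control array. The barcodes in the headers took only 3 distinct values and differed from the slide number of the array for 16 arrays, so slides were taken from the array names. Slide and scan day were each used as a fixed block. Control and 50 ng/L share 3 replicate codes, whose pairing was checked from the deviations from the group means.

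The alternatives were quantile normalization, normexp background correction with an offset of 50 on the median signal (a mean signal was not used here), the authors' values, other filters on dim probes, slide and replicate blocks, a random block of letter within group, array quality weights, a spread prior with trend and robust settings, only the groups compared, other thresholds, other trend scales, and each array left out in turn. Alternatives chosen after seeing the data were the scan day block, quantile normalization together with the slide block, a 2-level probe set as a covariate, the 2 arrays with the lowest median rank correlation left out, 1 probe per run of adjoining probe numbers, and outlier-flagged spots kept. All repeated fits filled flagged spots with the probe's mean over the other arrays of that group. This left every count past the adjusted threshold as it was and gave 7234 in place of 7231 probes at unadjusted p under 0.05 for 50 ng/L. Other groupings of the arrays were drawn 100 times per comparison.

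The fits were tested on simulated data that kept each probe's mean and residual SD over all 37244 probes, with 200 probes changed per comparison. Of the probes changed 2-fold, 35.8% were called at 0.5 ng/L, 52.2% at 5 ng/L, 56.7% at 50 ng/L and 52.2% for the trend. Of those changed 1.5-fold, 4.48%, 10.4%, 20.9% and 20.9% were called in the same order. Of those changed 4-fold, 87.9%, 89.4%, 93.9% and 92.4% were called. The simulated probes were independent, which real probes are not.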

Results

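Whole-fish transcripts were measured in 23 samples of inland silversides after 14 d with bifenthrin, a pyrethroid insecticide that acts on voltage-gated sodium channels, or with the solvent alone. The comparisons ask which transcripts differ at each nominal concentration and whether levels follow concentration. Levels are log2 signals relative to the 75th percentile of each array, and 37244 probes were tested. The probes named below had the smallest p on these same arrays. Their separation from the controls follows in part from that choice and is not separate support.

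At 50 ng/L, the probe CUST_6042_PI429335447 fell to 2.73-fold below the control level. Its mean was -3.75 ± 0.26 (SD, n = 7) against -2.30 ± 0.37 (n = 7) in controls, with a log2 change of -1.45 (SE 0.22, limma adjusted p = 0.0498), and all 7 exposed arrays lay below every control array. The adjoining probe CUST_6041_PI429335447, whose levels correlated with it at r = 0.947 across arrays, had a log2 difference of -1.39 (SE 0.27) that did not pass (limma adjusted p = 0.08). The higher probes with the smallest p did not pass either. CUST_2337_PI429335447 was above every control in 7 of 7 exposed arrays, with a mean of -3.60 ± 0.32 (n = 7) against -4.75 ± 0.39 (n = 7, limma adjusted p = 0.0612). It was not well above background on any control array, and by the bound it was 1.88-fold higher. On replicates A1 and B1 of 50 ng/L it was at -3.83 and -3.91, also not well above background. The bound is therefore not strict. CUST_22403_PI429335447 averaged -2.16 ± 0.31 (n = 7) against -3.18 ± 0.42 (n = 7), a 2.02-fold difference with a limma adjusted p of 0.08, and 6 of 7 exposed arrays exceeded every control.

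In all, 1 probe passed the adjusted threshold at 50 ng/L, a lower one. CUST_6042_PI429335447 no longer passed in 14 of 23 fits that each left out 1 array, and the count of probes ranged from 0 to 251 over these fits. Under the normexp settings, whose offset of 50 shrinks the folds of dim probes, its log2 difference was -0.30 with quantile normalization and -0.19 with the 75th percentile, and it did not pass. In the same order CUST_6041_PI429335447 stood at -0.19 and -0.05, CUST_2337_PI429335447 at 0.09 and 0.24 and CUST_22403_PI429335447 at 0.16 and 0.29. Without control B6, C3 or D2, or without replicate B5 of 50 ng/L, CUST_6041_PI429335447, CUST_2337_PI429335447 and CUST_22403_PI429335447 passed, with limma adjusted p between 0.0273 and 0.0491, and CUST_2337_PI429335447 also did without replicate B3 of 5 ng/L (0.0401). At unadjusted p under 0.05 there were 7231 probes, 19.4% of those tested, where 1862 would be expected with no change, and limma's convex estimate put 57.6% of probes as unchanged. Neither number takes account of the correlation between probes, so the estimate is not read as the share of probes that responded. Of the 7231, 60.4% were higher at 50 ng/L, but after quantile normalization 43.7% of 6872 were higher, so the balance of directions depends on the scaling. With slide as a block no probe passed, and 8418 were at unadjusted p under 0.05, of which 56.7% were higher. At unadjusted p under 0.01 the higher share was 68.8%, against 51.6% with slide as a block and 48.6% after quantile normalization. The 100 probes with the smallest p had a median log2 change, each in its own direction, of 0.96 over all arrays and of 0.61, 0.59 and 0.62 within slides 2, 3 and 5, the slides that held both groups. These probes were chosen on the same arrays.

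At 5 ng/L no probe passed in limma (smallest adjusted p = 0.138), and 4590 probes, 12.3%, were at unadjusted p under 0.05. The higher probe with the smallest p, CUST_26009_PI429335447, was not well above background on any of 7 control arrays and was well above it on all 5 exposed arrays. By the bound its level was 15.4-fold higher, with a mean of -0.56 ± 1.85 (n = 5) against -5.28 ± 0.92 (n = 7, limma adjusted p = 0.138). Replicate A8 lay far below the other 4 exposed arrays, and without it the bound was 26.9-fold and the probe passed (limma adjusted p = 0.0115). It also passed without replicate D4 of 0.5 ng/L (limma adjusted p = 0.00753). Under normexp with the 75th percentile it passed (limma adjusted p = 0.0238), but its log2 difference was 1.21, against 4.715 in the main values. With quantile normalization after normexp the difference was 1.08 and did not pass (limma adjusted p = 0.352). The probe was also well above background on 3 of 4 arrays at 0.5 ng/L and 2 of 7 at 50 ng/L. CUST_2337_PI429335447 was 1.84-fold higher by the bound, above every control on 5 of 5 arrays. Its log2 difference of 1.12 shrank under normexp to 0.10 with quantile normalization and 0.24 with the 75th percentile. The adjoining probes CUST_10010_PI429335447 and CUST_10011_PI429335447 were lower by 2.06-fold and 1.99-fold, below every control on 5 of 5 arrays, with limma adjusted p of 0.138 for both and of 0.0325 for both without A8. Under normexp with quantile normalization their log2 differences were -0.41 and -0.35, and with the 75th percentile -0.36 and -0.30. At 50 ng/L CUST_10010_PI429335447 averaged -0.92 ± 0.19 (n = 7), against -0.82 ± 0.26 (n = 7) in controls and -1.87 ± 0.50 (n = 5) at 5 ng/L.

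Of the 4590 probes, 67% were higher at 5 ng/L, against 49.1% of 4011 after quantile normalization. There were 5985 such probes with slide as a block, and none past the adjusted threshold. The 100 probes with the smallest p had a median log2 change of 0.94 over all arrays, 1.03 within slide 1 and 0.57 within slide 5. All 5 arrays at 5 ng/L were at the low level of the 2-level probe set described further on, and with that set as a covariate 1458 probes were at unadjusted p under 0.05, where 1853 would be expected.

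At 0.5 ng/L no probe passed in limma (smallest adjusted p = 0.0814), and 2560 probes, 6.87%, were at unadjusted p under 0.05. The adjoining probes CUST_29855_PI429335447 and CUST_29856_PI429335447 had the smallest p. They were 2.63-fold and 2.99-fold higher, above every control on 4 of 4 arrays, each with a limma adjusted p of 0.0814. These folds are limited by dim controls, of which 4 of 7 and 2 of 7 were well above background. The log2 differences were 1.40 (SE 0.23) and 1.58 (SE 0.26). Under the normexp settings these differences shrank to 0.20 and 0.17 with quantile normalization and to 0.49 and 0.48 with the 75th percentile. Both passed without replicate D4 of 0.5 ng/L (limma adjusted p of 0.0218 and 0.0296) and without control B1 (0.0431 for both), and CUST_29856_PI429335447 also did without control C3 (0.0421). For CUST_29855_PI429335447 the mean was -3.0 ± 0.48 (n = 4) against -4.40 ± 0.27 (n = 7). The lower probes with the smallest p were CUST_5521_PI429335447, at -3.99 ± 0.82 (n = 4) against -2.66 ± 0.32 (n = 7), and CUST_17907_PI429335447, which was not well above background at 0.5 ng/L and was 1.19-fold lower by the bound. Both had a limma adjusted p of 0.718. After normexp correction with the 75th percentile scaling, which moved the median of all probes to 0.18 in this comparison, they stood at 0.14 and 0.25, or -0.04 and 0.07 relative to that median. After normexp with quantile normalization both were lower, at -0.19 and -0.07.

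Of the 2560 probes, 58.2% were higher at 0.5 ng/L, against 39.4% of 2325 after quantile normalization. The number was 3483 with slide as a block, with none past the adjusted threshold, and without replicate B4 of this group it was 4842. The 100 probes with the smallest p had a median log2 change of 0.79 over all arrays, 0.90 within slide 1 and 0.76 within slide 2.

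The trend over concentration gave 6 probes past the adjusted threshold, 5 rising and 1 falling, and 7442 probes, 20%, at unadjusted p under 0.05. The group means of all 6 followed the order of concentration, a pattern for which the trend test selects. For the 4 probes that were well above background on all 7 control arrays, the fitted change from control to 50 ng/L ranged from 1.75-fold to 2.63-fold. The other 2 were not well above background on any control array, so the sizes of their slopes are not given. Among these, CUST_2337_PI429335447 was well above background on 0 of 7 controls, 1 of 4 arrays at 0.5 ng/L, 5 of 5 at 5 ng/L and 5 of 7 at 50 ng/L. CUST_22403_PI429335447 rose by 0.35 per step on the log2 scale (SE 0.06), from -3.18 through -2.66 and -2.20 to -2.16, and CUST_6042_PI429335447 fell by 0.47 per step (SE 0.07), from -2.30 through -2.64 and -2.88 to -3.75. These 3 probes each had a limma adjusted p of 0.0419. Under normexp with quantile normalization and with the 75th percentile, the slope was 0.06 and 0.09 for CUST_22403_PI429335447 and -0.10 and -0.07 for CUST_6042_PI429335447, and only the latter passed, with quantile normalization (limma adjusted p = 0.0452). CUST_6041_PI429335447 had a slope of -0.44 (SE 0.08) and did not pass (limma adjusted p = 0.0508). It passed in 5 of 16 alternative settings and in 9 of 23 fits that left out 1 array, and not in the others. Over the exposed groups alone, with fewer arrays, no probe passed in limma. There, 2008 probes were at unadjusted p under 0.05, where 1862 would be expected with no change. The large excess in the trend was thus not seen without the controls.

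The number of trend probes moved with the processing. With slide as a block 0 passed, with scan day as a block 1 passed that was not among the 6, with outlier-flagged spots kept 71 passed, and leaving out single arrays gave from 0 to 976. Of the 7442 probes, 61.6% had a rising slope, against 45.7% of 7117 after quantile normalization.

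**Figure D1:**
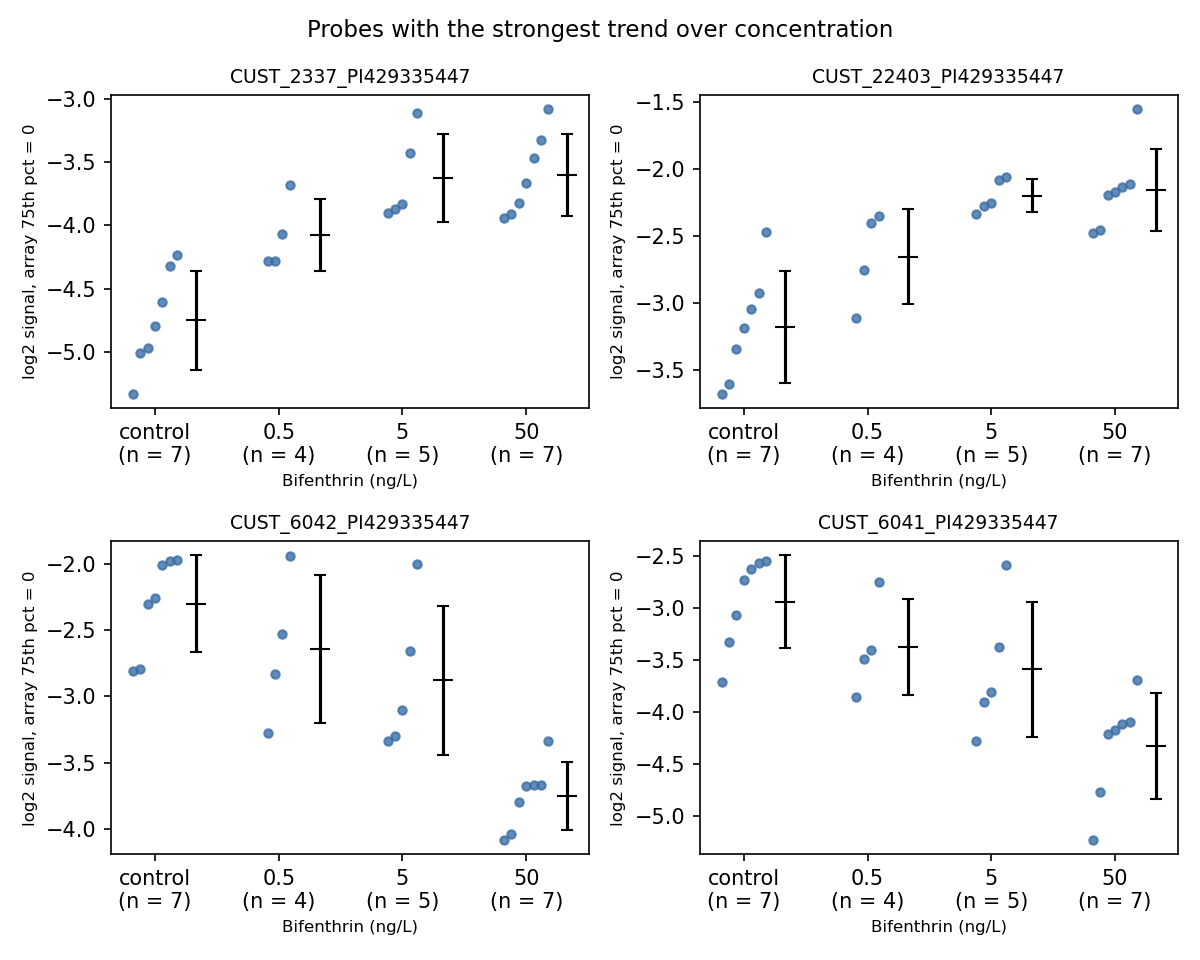
Log2 signal (array 75th percentile set to 0) of the probes with the smallest trend p, 2 higher and 2 lower, by bifenthrin concentration in ng/L. Points are arrays, sorted by level within a group, and the bars are the mean ± SD; all 7 arrays at 50 ng/L lie below every control for CUST_6042_PI429335447, and no control array was well above background for CUST_2337_PI429335447.

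The concentrations were also compared with each other. No probe passed between 0.5 and 5 ng/L, between 0.5 and 50 ng/L, or between 5 and 50 ng/L in limma, with smallest adjusted p of 0.999, 0.305 and 0.645. At unadjusted p under 0.05 there were 1044, 1727 and 1378 probes, which is 2.8%, 4.64% and 3.7% of those tested. The F test of the 4 groups passed no probe (limma smallest adjusted p = 0.174), with 4059 probes, 10.9%, at unadjusted p under 0.05. These 4 counts past the threshold were also 0 with slide as a block.

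**Figure D2:**
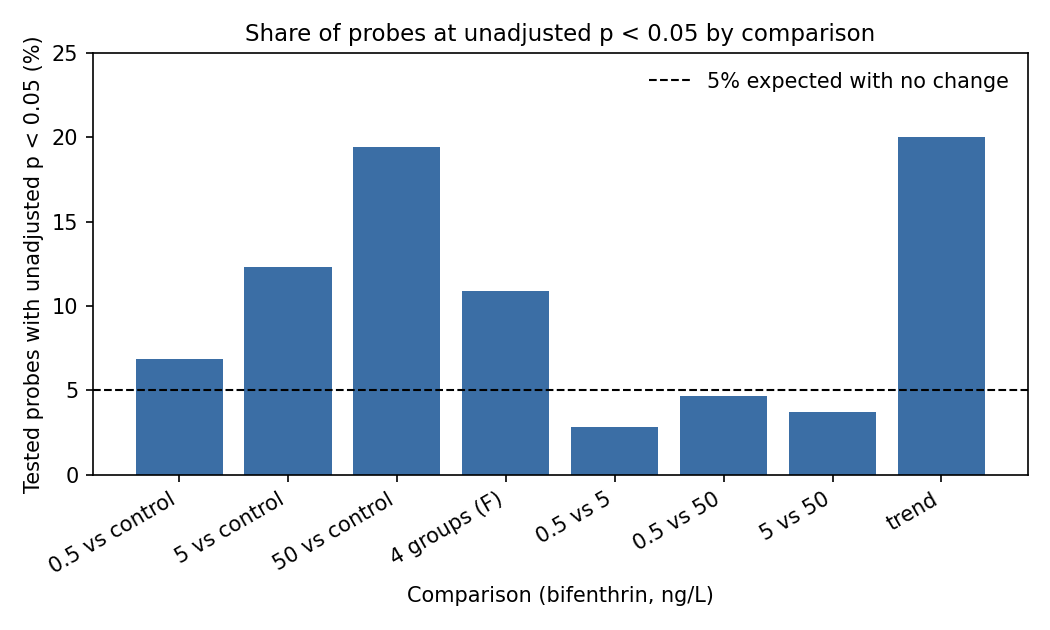
Percent of the 37244 tested probes at unadjusted p under 0.05 in each comparison, with concentrations in ng/L; the dashed line is the 5% expected with no change. The bars against control rise from 6.87% at 0.5 ng/L to 19.4% at 50 ng/L, and the bars between concentrations lie below 5%. The exposed groups also grow with concentration (n = 4, 5 and 7), and the median SE falls from 0.254 at 0.5 ng/L to 0.217 at 50 ng/L. Equal changes would therefore reach this p more often at 50 ng/L.

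Fold changes against control correlated across probes at r = 0.636 between 0.5 and 5 ng/L, 0.657 between 0.5 and 50 ng/L and 0.665 between 5 and 50 ng/L. Probes are not independent replicates, and the comparisons share their controls. Unchanged groups simulated against the same number of controls gave 0.388, 0.426 and 0.455. The covariances were 0.113, 0.0984 and 0.131, against simulated values of 0.0466, 0.0468 and 0.0467. The simulated probes were independent, which real probes are not. The simulation therefore cannot show how far r or the covariance of unchanged groups would vary, and no shared response is read from it. With the controls divided so that each comparison had its own, the median r over 70 divisions was 0.335 (range -0.06 to 0.54), 0.265 (0.08 to 0.43) and 0.398 (-0.01 to 0.59) in the same order. Without replicate D4 of 0.5 ng/L, the first correlation was 0.406.

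A set of 184 probes, the largest cluster among the 400 most variable probes, stood at 2 separate levels. This set was found after seeing the data. Its mean level lay between -4.48 and -3.57 on 12 arrays and between -0.14 and 2.23 on 11 arrays, a gap of 3.42 on the log2 scale, or 10.7-fold. On the low arrays 55 to 98 of the 184 probes were well above background, against 173 to 184 on the high arrays. The size of the gap is therefore limited by background. The high level was seen in 5 of 7 controls, 2 of 4 arrays at 0.5 ng/L, 0 of 5 at 5 ng/L and 4 of 7 at 50 ng/L. The group means were -0.30 ± 2.82 (n = 7), -1.67 ± 2.99 (n = 4), -4.05 ± 0.39 (n = 5) and -1.19 ± 3.0 (n = 7). Against control, exact two-sided permutation tests gave p = 0.439 at 0.5 ng/L, 0.0303 at 5 ng/L and 0.557 at 50 ng/L, or 0.557, 0.0909 and 0.557 after Benjamini-Hochberg adjustment over these 3 tests.

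**Figure D3:**
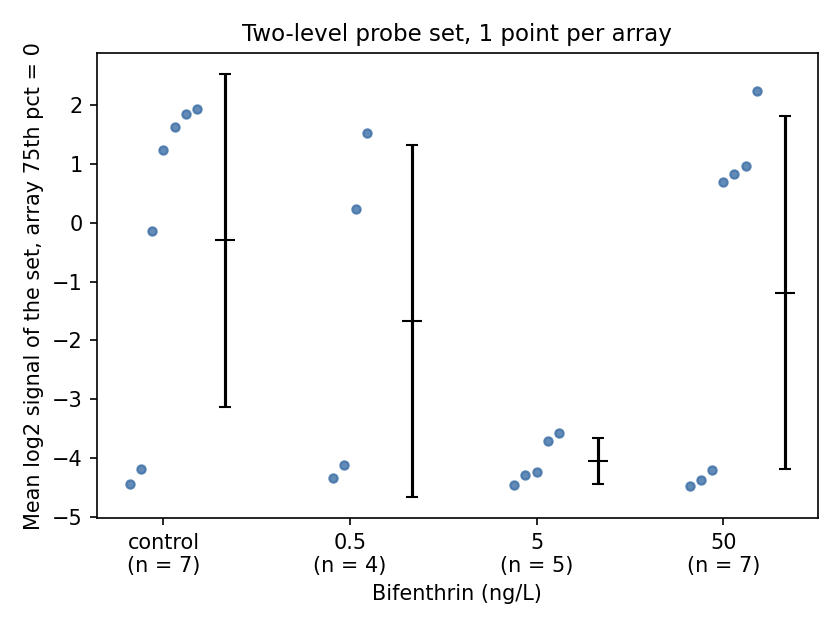
Mean log2 signal (array 75th percentile set to 0) of the 184-probe set by bifenthrin concentration in ng/L. Points are arrays and bars the mean ± SD; all 5 arrays at 5 ng/L lie at or below -3.57, and the other groups hold both levels.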

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

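Of 60 sets of values (11 named probes, 3 array measures and the 2-level probe set, in each of 4 groups), 4 held an array that lay far from the rest of its group. Chance alone gives about 1 in 20. The rule was set before the data were examined, and the 2-level set was added after seeing the data.

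CUST_26009_PI429335447 was at -3.77 on replicate A8 of 5 ng/L, while the other 4 arrays lay between -0.24 and 0.74. CUST_5521_PI429335447 was at -4.51 on replicate C4 of 5 ng/L, against -3.40 to -2.97 on the other 4 arrays. CUST_10011_PI429335447 was at -0.38 on control D3, against -1.13 to -0.84 on the other 6. CUST_22403_PI429335447 was at -1.56 on replicate D1 of 50 ng/L, against -2.48 to -2.12 on the other 6, and D1 is also among the 2 arrays with the lowest rank correlation with the rest.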

How the results depend on the processing

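The scan day block, quantile normalization together with the slide block, the 2-level set as a covariate, the 2 arrays with the lowest rank correlation (0.5 ng/L B4 and 50 ng/L D1) left out, 1 probe per run of adjoining numbers, and flagged spots kept were chosen after seeing the data. The main setting leaves flagged spots out, and this too was set after the counts with them kept had been seen. The causes of the changes below were not tested, except where fewer probes or arrays entered the test. No gene list, oocyte covariate or list test was run, because no probe has a gene name here. Many named probes lie near background, which limits their folds. Of the 11 named probes, CUST_5521_PI429335447 and CUST_17907_PI429335447 at 0.5 ng/L stood at 0.136 and 0.246 on the log2 scale under normexp with the 75th percentile, a setting that moved the median of all probes in that comparison to 0.176, and at -0.189 and -0.066 under normexp with quantile normalization. Every other named probe kept its direction where it was tested, but sizes shrank under both normexp settings, whose offset of 50 pulls the folds of dim probes toward 0. With quantile normalization and with the 75th percentile after normexp, the log2 difference at 50 ng/L was -0.3 and -0.188 for CUST_6042_PI429335447 (-1.45 in the main values) and -0.185 and -0.054 for CUST_6041_PI429335447 (-1.39), and at 0.5 ng/L it was 0.195 and 0.492 for CUST_29855_PI429335447 (1.40) and 0.17 and 0.483 for CUST_29856_PI429335447 (1.58). The authors' processed values hold none of the named probes, and the filter on all arrays holds only some.

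The count past the adjusted threshold at 50 ng/L (1) was 0 with normexp and quantile normalization, normexp and the 75th percentile, the authors' processed values, no filter on dim probes, only probes well above background on all arrays, slide as a block, the random block of group and letter, eBayes with trend and robust settings, the 2-level set as a covariate, and flagged spots kept. It was 2 with array quality weights, 2 with 1 probe per run of adjoining numbers, 4 with only the 2 groups compared, and 959 at an adjusted p under 0.1. The count for the trend (6) was 2 with quantile normalization, 1 with normexp and quantile normalization, 0 with normexp and the 75th percentile, 160 with the authors' processed values, 505 with only probes well above background on all arrays, 0 with slide as a block, 0 with the random block, 198 with eBayes trend and robust settings, 346 with array quality weights and 1533 at an adjusted p under 0.1. It was 1 with the scan day block, 1 with quantile normalization and slide, 1 with the 2-level set, 307 with 1 probe per run, 0 without the 2 arrays, 71 with flagged spots kept, 0 on nominal concentrations in ng/L and 0 with exposed groups only. All 6 main probes were among the 346, the 198 and the 71. Only 3 were tested under the filter on all arrays and 1 in the authors' values, and these were among the 505 and the 160. None of the 6 was the probe that passed with the scan day block or with quantile normalization and slide. At 50 ng/L these settings also passed 1 probe other than CUST_6042_PI429335447, whose adjusted p was 0.0643 and 0.103 there, in a range of 0.00578 to 0.585 over its alternatives, apart from single arrays left out. Normexp with the 75th percentile gave 2 probes at 5 ng/L and 2 in the F test, and 1 probe per run gave 2 at 0.5 ng/L, as did an adjusted p under 0.1. At unadjusted p under 0.01, there were 470, 1100 and 2611 probes at 0.5, 5 and 50 ng/L, 1016 in the F test, 153, 309 and 190 between concentrations, and 2785 in the trend.

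The counts at unadjusted p under 0.05 at 0.5, 5 and 50 ng/L and in the trend were 480, 797, 1581 and 1670 with the authors' processed values, which hold fewer probes, and 1675, 2932, 4614 and 4748 with 1 probe per run, which tests 21780. With normexp and the 75th percentile they were 11664, 2543, 4816 and 4012. At 0.5 ng/L the count was 4532 with array quality weights and 5339 without the 2 arrays, and at 5 ng/L it was 1458 with the 2-level set. The trend count was 4287 on nominal concentrations and 2008 with exposed groups only, where 1862 would be expected with no change. The correlations of fold changes were 0.554 for 0.5 and 5 ng/L and 0.558 for 0.5 and 50 ng/L with the authors' processed values.

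Whether the 3 replicate codes shared by control and 50 ng/L pair the samples stays open. Deviations of same-coded arrays correlated at -0.271, 0.176 and 0.191, against a mean of -0.001 for differently coded pairs of these groups. So few correlations cannot decide it, and the labels do not say what the codes mean. As a block, the letter of the code gave 0 probes at 50 ng/L and 105 in the trend, and the 3 shared codes as pairs gave 0 probes past the threshold and 3170 at unadjusted p under 0.05, from 6 arrays.

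Each array was left out in turn, in 23 fits. The count at 50 ng/L ranged from 0 to 251. It was 0 without control A2, C7 or D3, 0.5 ng/L D4 or D6, 5 ng/L A6, C2 or C4, or 50 ng/L A1, A2, B1, C3, D1 or D5, and 2 without 5 ng/L B3, 130 without 50 ng/L B5, 164 without control C3, 218 without control D2 and 251 without control B6. The trend count ranged from 0 to 976. It was 0 without control A2, C7 or D3, 0.5 ng/L D6, 5 ng/L A6, or 50 ng/L A1, B1, D1 or D5, 1 without 0.5 ng/L A7 or 5 ng/L C4, and 2 without control B1 or 5 ng/L B3 or C2. It was 49 and 241 without 0.5 ng/L D4 and B4, 591, 604 and 976 without 50 ng/L B5, C3 and A2, and 616, 769 and 851 without control C3, B6 and D2. The count at 0.5 ng/L ranged from 0 to 4, with 4 without 0.5 ng/L D4, 2 without control B1 or C3 and 1 without 5 ng/L B3. That at 5 ng/L ranged from 0 to 7, with 7 without 5 ng/L A8 and 2 without 0.5 ng/L D4. The F test ranged from 0 to 3, with 3, 2 and 1 without 5 ng/L A8, 0.5 ng/L D4 and 50 ng/L A1. Between 0.5 and 50 ng/L 1 probe passed without 50 ng/L A1, and between 5 and 50 ng/L 1 passed without 5 ng/L A8. At unadjusted p under 0.05, the count at 0.5 ng/L ranged from 1913 to 4842, the highest without 0.5 ng/L B4; those at 5 ng/L, 50 ng/L and in the trend ranged from 3436 to 5163, 5267 to 8838 and 5552 to 9217. The correlations ranged from 0.406 to 0.713 for 0.5 and 5 ng/L, 0.512 to 0.706 for 0.5 and 50 ng/L and 0.577 to 0.729 for 5 and 50 ng/L, the lowest without 0.5 ng/L D4, 0.5 ng/L D4 and 50 ng/L D1.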

Other observations

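The tests of slide, scaling and dim probes, of the levels of the 184-probe set, of adjoining probes, and of the groupings for counts past the adjusted threshold other than the trend were chosen as tests of these patterns after their results were seen, although the fits with slide as a block and with quantile normalization were themselves set before the data were examined. The scan day block and the 2-level set as a covariate were added after seeing the data, the latter with its criterion written before its result.

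Probes with adjoining numbers tended to move together. Over 34697 adjoining pairs the median correlation across arrays was 0.738, and 44.6% of pairs exceeded 0.8. Among 5000 random pairs 0.28% exceeded 0.8. Joining adjoining probes with r over 0.8 left 21780 runs. Whether adjoining numbers mark the same transcript was not tested, since the probes have no gene names here. The 6 trend probes fell in 6 runs. CUST_2337_PI429335447 and the other trend probe not well above background on any control array lie 2 numbers apart, and both rose. No probe between them was tested, so they could not be joined. The 6 runs therefore need not be 6 separate signals. Among the tested probes, 146 had a gap of at least 2 log2 units with at least 4 arrays on each side, and 102 of these divided the arrays exactly as the 184-probe set did. A run of 5 probes was high on 9 arrays, namely 3 controls, 2 at 0.5 ng/L, 1 at 5 ng/L and 3 at 50 ng/L.

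The excess of probes at unadjusted p under 0.05 for 50 ng/L was weighed against 3 technical explanations. With slide as a block there were 8418 such probes, with quantile normalization 6872, and with the 2-level set as a covariate 6702, all far above the 5% expected (1862, or 1853 with the set left out). None of these corrections, taken one at a time, brought the count near that number. The 5% takes no account of the correlation between probes, and the highest other grouping of these arrays reached 9151 without a correction. No other groupings were fitted with the corrections. The counts therefore cannot settle whether slide, scaling or the set is the whole cause. An effect of exposure remains open as a hypothesis, together with chance, and with tank, body size and sex, which the labels do not give.

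At 50 ng/L, 68.8% of the 2611 probes at unadjusted p under 0.01 were higher. After quantile normalization 48.6% were, and with the scaling kept 51.6% were with slide as a block and 57.8% with scan day as a block. With quantile normalization and the slide block together 34.6% were higher, so most were then lower. Scaling or slide may each account for this imbalance, and which of them does stays open. Under the 75th percentile scaling the dimmest 1 of 5 equal groups of probes by brightness had a median log2 shift of 0.18 at 50 ng/L, against 0.01 after quantile normalization. Among probes brighter than the median 60.2% were higher, which lies between the values set for and against an effect of dim probes alone, so that question stays open.

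The 2 levels of the 184-probe set do not follow the slide, since 5 of 6 slides held both levels, and exposure alone does not set them, since 3 of the 4 groups, controls included, held both. That criterion was written after the tally per group had been seen. A link with 5 ng/L stays open: 0 of 5 arrays there and 5 of 7 controls were at the high level, with an exact permutation p of 0.0303 for the set's mean, or 0.0909 after adjustment. The permutations ignored scan day. All 3 scan days held both levels, but on 1 of them every array except replicate B1 of 50 ng/L was low. That day held replicates A6, A8 and C4 of 5 ng/L and, of the controls, only B6. Array brightness cannot produce the gap by scaling, since the brightest array exceeded the dimmest 1.94-fold and the gap was 10.7-fold. The latter fold is limited by background on the low arrays. No biological explanation was tested, because the design names only exposure and the probes have no gene names here.

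Other groupings of the same arrays were fitted 100 times per comparison, the real one included. The 7448 trend probes at unadjusted p under 0.05 were reached by 1 grouping, the real one, and the highest other gave 7197. For 50 ng/L the count of 7234 was reached by 4 groupings, with 9151 in the highest other, and for 5 ng/L the count of 4592 was reached by 2, with 5242 in the highest other. Each of these 3 counts was reached by fewer than 5% of the groupings. These shares were not corrected for the number of counts tested, and the 3 counts share arrays. The groupings also ignore slide, which explained 38.1% and 54.3% of the variance of the real labels at 50 and 5 ng/L. Shares of variance are not adjusted for the number of slides. With 6 slides and so few arrays, labels drawn at random would also give large shares. How far slide sets the labels is therefore not read from them. The shares of groupings alone do not exclude chance. With slide as a block the counts were 8637 for the trend, 8418 at 50 ng/L and 5985 at 5 ng/L. At 5 ng/L the 2-level set explained 45.9% of the variance of the real group label, and with the set as a covariate the count was 1458, below the 1853 expected, so the excess at 5 ng/L is not separated from the set. For 0.5 ng/L 29 groupings gave as many as 2564, with up to 7117, so chance is not excluded. Of the counts past the adjusted threshold, the 6 trend probes were reached by 2 groupings, with 254 in the other. This share too is uncorrected and comes from groupings that ignore slide. The groups are uneven over slides, with no control array on slides 4 and 6. Slide explained 23.2% of the variance of the real concentration rank, a share that is likewise not adjusted for the number of slides. With slide as a block 0 probes passed, with scan day 1 that was not among the 6, and without 1 array 0 passed in 9 of 23 fits, so these 6 calls do not hold across these settings. The 1 probe at 50 ng/L was reached by 6 groupings, with up to 366, so chance is not excluded. A count of 0 is reached by every grouping by definition, so for the counts of 0 the groupings do not test chance. The highest others there were 356 at 0.5 ng/L, 504 at 5 ng/L and 2 for the F test. Between concentrations they were 6 for 0.5 and 5 ng/L, 2291 for 0.5 and 50 ng/L and 3 for 5 and 50 ng/L.

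Some groupings gave many more probes than the real one, which may point to a structure of the samples. Shares of variance were computed only for the real and the highest other grouping, and no test of such a structure was run. Those for slide and scan day are not adjusted for the number of slides or days, so they are not comparable with those for the set. In the grouping with 504 probes, the level of the 2-level set explained 96% of the variance of the group label, against 45.9% in the real one, and in the trend grouping with 254 probes 56.8%, against 4.04%. In the grouping with 9151 probes it explained 1.36% and slide 52.4%, against 38.1% for slide in the real one, where the slide-blocked count was 8418. In the grouping with 2291 probes between 0.5 and 50 ng/L the set explained 1.16% and slide 41.1%, against 54.2% for slide in the real one. In that with 356 probes at 0.5 ng/L they explained 4.55% and 34.5%, against 47.6% for slide in the real one, while scan day explained 32.7%, against 6.46% in the real one.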
